A study of Medicago truncatula with 2 samples.

How the data were processed

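RNA from whole nodules of the legume Medicago truncatula was sequenced in 2 samples, 1 of the wild-type line A17 and 1 of the mutant dnf7-2, per the labels. Plants were grown aeroponically and inoculated with the nitrogen-fixing bacterium Sinorhizobium meliloti WSM419, and the sample titles give 17 days. Per the labels' protocols, DNase-treated total RNA was depleted of ribosomal RNA, fragmented, made into SOLiD libraries and read as 50-base sequences on a SOLiD 5500xl instrument. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here.

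The deposited table holds the authors' comparison of the genotypes. The submitters' processing notes name DESeq with no version. Per the file headers, the columns are those of its negative binomial test. The deposited signal columns are the authors' mean normalised read counts per genotype, which are reads divided by a size factor. The authors' fold column is the ratio of the second mean to the first, and the authors' log2 column is the log2 of that ratio. The deposited p-value columns hold the authors' p and its adjusted value. Per the file headers the means are called A and B. That A is A17 and B is dnf7-2 rests on the order in which the deposited comparison names the lines, and every direction given here depends on it. The assignment was not made from the values. NCR169, the gene at DNF7, is lower in B, which is the direction the assignment predicts for a mutant that lacks the transcript. Loss of the transcript in dnf7-2 is assumed here, so the low value is no independent check of the order.

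Each of the 51576 values in either mean column was a sum of whole multiples of 2 steps, with exactly 1 solution per value within a tolerance of 2e-09 reads plus 2e-12 of the value, and a largest error of 1.53e-09 reads. Each value also had 1 solution at a tolerance of 1e-06 reads. Each mean was therefore taken apart into 2 component libraries per genotype, called deeper and shallower by their total. On simulated data for the 51576 features the procedure returned 100% of the pairs of counts in either genotype. The labels do not say whether the components are separate plants, preparations or sequencing runs, so no test between the genotypes treats them as replicates. Within a genotype they differed by more than counting error, with a median chi-square per gene of 6.56 in A17 and 4.11 in dnf7-2 where counting error alone gives 0.455. These values argue against repeat runs of 1 library that differ by counting error alone. They leave separate plants and separate preparations open. Their values are given as a measure of spread, the genotype means are given as the authors' means, and p-values for genes are those in the authors' deposited table. For the fixed lists, the unadjusted p of that table was also adjusted by the Benjamini-Hochberg method over the members at the expression minimum alone. If the authors' test took the components as replicates, and these are technical, each such p measures technical spread and not that between plants.

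The design written before the data were examined assumed 1 library of counts or normalised values per genotype. The deposited means were used as they stand. Ratios are dnf7-2 over A17 on the log2 scale with a pseudocount of 1, which understates the change of low genes. Counts of genes took features with a mean of at least 50 over both genotypes and a threshold of 4-fold. Intervals are exact 95% intervals on reads and cover counting error only, since reads amplified by PCR are not independent molecules.

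Of 25 gene lists fixed before the data were examined, 22 had no member because they search annotation text and the table carries identifiers alone. Every list of markers for other nodule cell types is among these 22. The lists with members were the features whose identifier is an NCR number, 17 loci of nodulation signalling and transcription, and 6 loci of symbiosis persistence. The symbols of those 23 loci come from general knowledge; neither the table nor the reference pairs them with the identifiers. The reference gene table, assembly MtrunA17r5.0-ANR, held 0 of the table's identifiers. By symbol it matched 10 of the 23, of which 1 (NAD1) matched only a mitochondrial gene of the same letters and was set aside after the match was seen; the other 9 lay on the chromosome that the identifier names. A list median was set against 10000 random lists of the same size matched on mean expression in 20 bins, and stood apart below the 2.5 or above the 97.5 percentile. In simulated lists of 20 genes, 2.5% of 40 unshifted lists, 95% of 40 lists shifted by 0.5 on the log2 scale and 100% of 40 shifted by 1 stood apart. Their genes were picked at random and the ratios shuffled among genes of like expression. They do not show how often a list of genes that change together would stand apart.

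Genes are named by a rule: the members of the fixed loci, NCR-named features, and the 8 highest and 8 lowest ratios at a mean of at least 200. Because the identifiers of the last group are not paired with names, it is summarised and at most 2 identifiers each way are printed, chosen after their values were seen. The alternatives were scaling to column totals, a trimmed mean of M values written for this purpose (30% and 5% trimmed), centring on the median ratio, other expression minimums, pseudocounts of 10 and 0.5, a 2-fold threshold, other list summaries and, added after the data were seen, leaving out each component. In the tests of explanations, a bound was taken as passed only where the 95% bootstrap interval (10000 resamples) lay beyond it. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The 4 rows that name no gene were left out of lists and gene counts; they held 0.000922% to 0.00362% of the reads of a component.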

Results

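Transcript levels were measured in whole nodules of A17 and of dnf7-2, a mutant of the DNF7 locus, which encodes the nodule cysteine-rich peptide NCR169. The series title frames the question as whether bacteria can persist in the zone of the nodule that fixes nitrogen when DNF7 is lost. There was 1 deposited sample per genotype. The component libraries recovered from the authors' means held 18403696 and 4610467 reads in A17, and 12318309 and 2711405 reads in dnf7-2. Reads fell on 35724 named features, of which 15352 had a mean of at least 50 normalised reads.

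NCR169 transcript was almost absent from dnf7-2 nodules. Its mean (MTR_7g029760) fell from 7879 normalised reads in A17 to 10.9 in dnf7-2, which is 0.139% of the A17 level, with an adjusted p of 9.15e-06 in the authors' deposited table. In reads, the A17 components held 17674 and 2872 and the dnf7-2 components 27 and 1. The summed reads gave 0.180% of the A17 level (95% interval 0.120% to 0.260%). The percentage was 0.0424% without the deeper dnf7-2 component and 0.235% without the shallower one. The expressed loci on either side, named for their position, were not silent: MTR_7g029630 was at 108% and MTR_7g031160 at 130% of the A17 mean. Loci with an A17 mean under 20 were passed over in choosing them. Whether such loci nearer to NCR169 were lost was therefore not assessed. Among 17922 loci with an A17 mean of at least 20, 24 were under 5% of it in dnf7-2, and no 2 of them were neighbours. With the genotypes exchanged, the longest run was 2 loci.

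**Figure D1:**
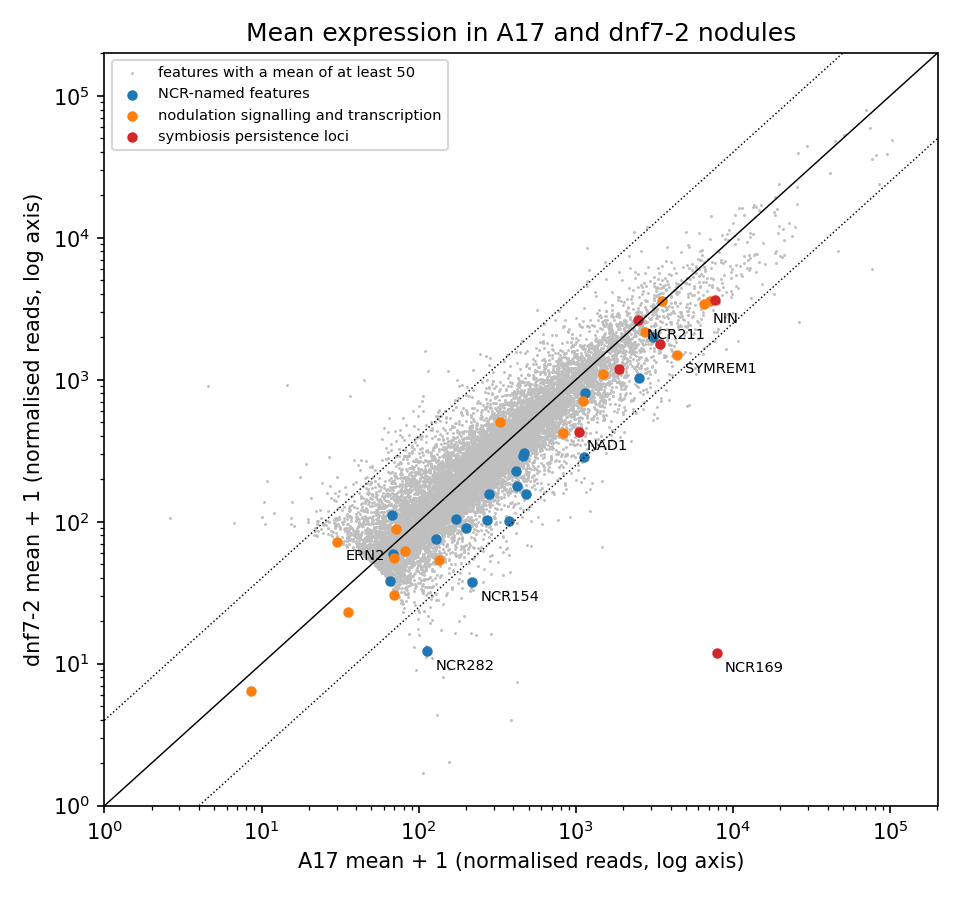
Authors' mean normalised reads plus 1 in A17 (x, log axis) and dnf7-2 (y, log axis). Each grey point is a feature with a mean of at least 50, and dotted lines mark 4-fold. Coloured points are the 23 fixed loci, including those below that mean, and the 20 NCR-named features at or above it. NCR169 lies farthest below the line of equal expression among the list members, at 7879 against 10.9 normalised reads.

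Other genes named for nodule cysteine-rich peptides, secreted peptides that nodule cells direct to their bacteria, were mostly lower in dnf7-2. The list holds only features whose identifier is an NCR number. NCR169 and NCR211 stand under other identifiers and are outside it, so its counts describe this named subset and not the family. Of 47 NCR-named features, 24 were detected and 20 passed the expression minimum; 19 were lower in dnf7-2 and 1, NCR267, was higher. Their median log2 ratio was -0.85, below each of the 10000 matched random lists, whose central 95% ran from -0.33 to 0.23. Random lists were matched on mean expression alone, so this range does not allow for members that change together. With 1 deposited sample per genotype, the place of this and of the other lists describes the 2 samples and not the genotypes. At least 2-fold lower were 9 of them. NCR282 stood at 113 against 11.2 normalised reads in A17 and dnf7-2, NCR154 at 218 against 36.5, and NCR277 at 1131 against 285, while NCR261 was at 26.8% of its A17 level. As 1 component was left out, NCR282 was between 5.25-fold and 16.8-fold lower and NCR154 between 5.02-fold and 7.39-fold lower. NCR226 and NCR366 were higher in dnf7-2 in at least 1 leave-out. NCR267 stood at 66.3 against 111. The abundant NCR028 was at 3113 against 1992, with overlapping components and a fold of 1.07 to 2.90 as 1 component was left out. Both components of one genotype lay beyond both of the other in 12 of the lower features and in NCR267. Scaling to column totals, which raised every log2 ratio by 0.19, left 19 lower and 1 higher.

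None of the 20 passed an adjusted p of 0.05 over all genes in the authors' deposited table, and 4 had an unadjusted p under 0.05 there. Adjusted over the list alone, the p-values of the authors' deposited table passed for 3, all lower: NCR154 at 0.00305, NCR277 at 0.0155 and NCR261 at 0.0271. NCR282, the lowest ratio, had an unadjusted p of 0.266 in the authors' deposited table.

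**Figure D2:**
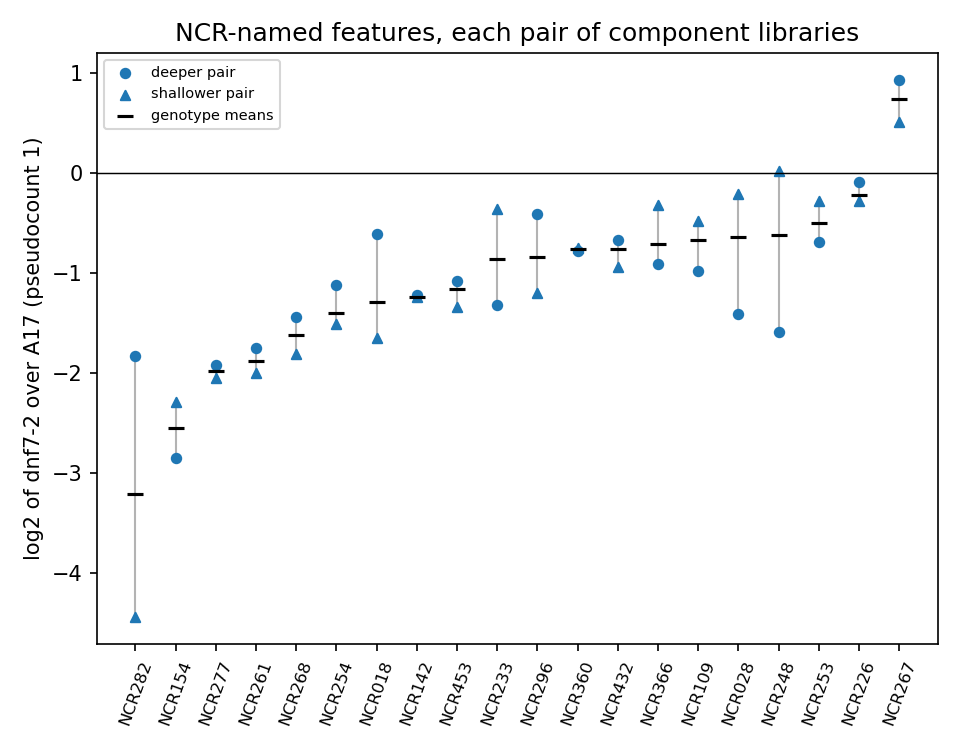
Log2 of dnf7-2 over A17 with a pseudocount of 1 for the 20 NCR-named features at the minimum; circles are the ratio of the deeper components, triangles that of the shallower components, and dashes that of the authors' means. By the means 19 features lie below 0 and NCR267 lies above it at 0.73.

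Genes of nodulation signalling and transcription leaned lower in dnf7-2 without standing apart from random lists. Of 14 members at the minimum, 10 were lower and 4 higher, with a median log2 ratio of -0.42 at percentile 4.86. SYMREM1, a remorin of infection threads, was at 4385 normalised reads in A17 and 1500 in dnf7-2. NIN, the transcription factor that starts nodule formation, was at 6561 against 3417, and IPD3, a nuclear partner of the kinase DMI3, at 7138 against 3584. DMI1, a nuclear ion channel, was at 134 against 52.8. NSP2, a GRAS transcription factor below the expression minimum and so outside the 14, was at 68.3 against 29.7. VPY, which acts in infection, was at 823 against 420. As 1 component was left out, the log2 ratio ran from -2.10 to -1.15 for SYMREM1, from -1.51 to -0.53 for NIN and from -1.65 to -0.54 for IPD3.

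Other members at the minimum were closer to parity than these, or higher. EFD, an ERF transcription factor, was at 1116 normalised reads in A17 and 706 in dnf7-2. The receptor kinase DMI2 was at 3543 against 3599, DMI3 at 1479 against 1089 and NF-YA1 at 2742 against 2175. LYK3 was at 80.4 against 61.1 and ENOD11 at 68.7 against 54.6, both with overlapping components. As 1 component was left out, the log2 ratio ran from -0.79 to 0.16 for LYK3 and from -0.84 to 0.46 for ENOD11. Both were higher in dnf7-2 without the deeper A17 component, though counted among the lower members. ERN2, another ERF transcription factor, was at 29.1 against 71.4, ERN1 at 70.6 against 88.1, and NSP1 at 328 against 503. The A17 components of ERN2 were 12.3 and 45.9, and its log2 ratio of 1.26 ran from 0.63 to 2.44 as 1 component was left out; that of NSP1 ran from 0.19 to 1.18 and that of ERN1 from -0.10 to 0.64. The components of the genotypes did not overlap in 8 of the lower members and in 1 higher member. No member passed an adjusted p of 0.05 over all genes in the authors' deposited table and 5 had an unadjusted p under 0.05 there. Adjusted over the list alone, 1 passed, SYMREM1 at 0.0297. The median stood apart, at -0.79 and percentile 0.13, without the shallower A17 component and, at -0.70 and percentile 1.52, without the shallower dnf7-2 component. It did not stand apart without the deeper A17 component (-0.39, percentile 5.2) or the deeper dnf7-2 component (-0.29, percentile 16.83).

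Loci whose loss is known to stop bacteria from being kept in the nodule were lower in dnf7-2 except for NCR211. SYMCRK, a receptor-like kinase, was at 7652 normalised reads in A17 and 3666 in dnf7-2, DNF2 at 3438 against 1789, and NAD1 at 1042 against 429. DNF1, a subunit of the signal peptidase complex, was at 1875 against 1192, while NCR211 was at 2492 against 2626. The components of the genotypes did not overlap in 4 of the lower loci, NCR169 among them. They overlapped in DNF2, at 2315 and 4560 in A17 and 1132 and 2446 in dnf7-2, and its log2 ratio ran from -1.60 to -0.37 as 1 component was left out. For NCR211 the dnf7-2 components at 1324 and 3927 lay on either side of the A17 components at 2121 and 2864. The 6 loci had a median ratio of dnf7-2 over A17 of 0.499, at percentile 0.92. Without NCR169, the mutated gene itself, the others had a median log2 ratio of -0.94 at percentile 2.84, which no longer stood apart. The list also lost its place without the shallower A17 component (-0.62, percentile 9.54) or the deeper dnf7-2 component (-0.57, percentile 7.08). NCR169 alone passed over all genes in the authors' deposited table; adjusted over the list alone, NAD1 passed too, at 0.0293. That adjustment kept NCR169, the mutated gene itself, among the 6 loci, which lowers the adjusted value of NAD1.

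**Figure D3:**
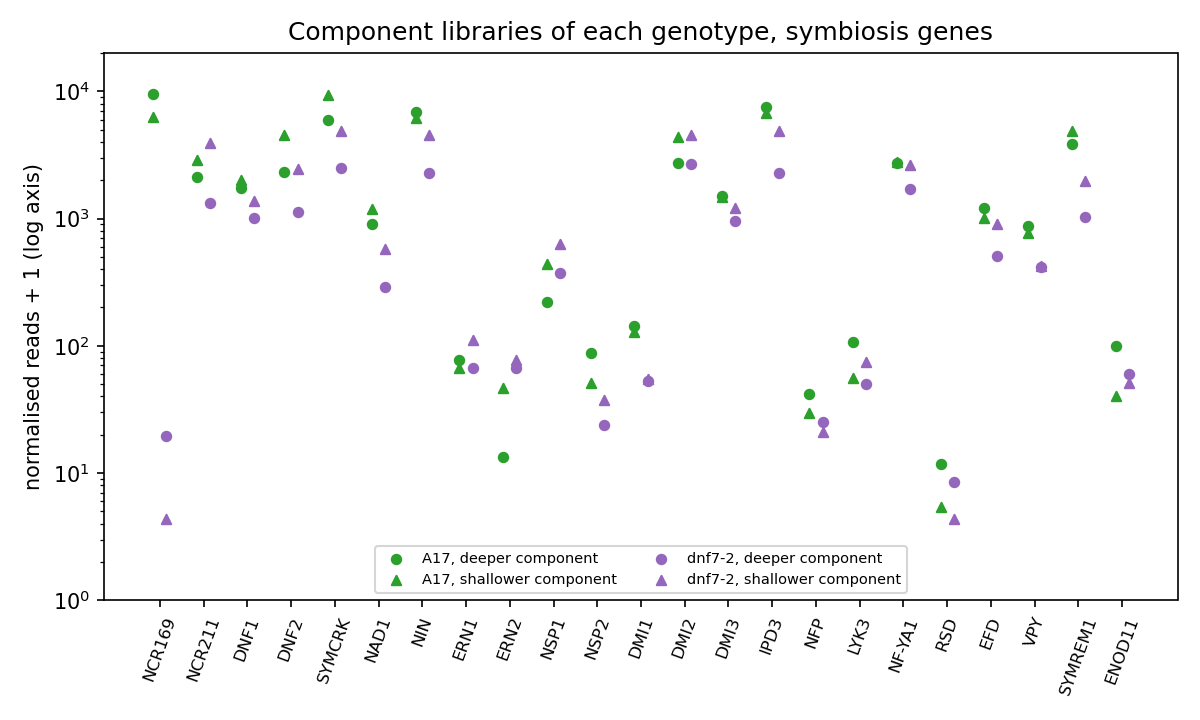
Normalised reads plus 1 (log axis) of the 2 component libraries of A17 (green) and of dnf7-2 (purple) for the 23 fixed loci; circles are the deeper and triangles the shallower components. NCR169 is the locus with the widest gap between genotypes, and for NCR211 the dnf7-2 components enclose those of A17.

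Across the transcriptome, few genes differed strongly. At least 4-fold higher in dnf7-2 were 121 genes and at least 4-fold lower 144, together 1.73% of the 15352. In the authors' deposited table, 48 of 35724 tested features had an adjusted p under 0.05, of which 30 rose and 18 fell in dnf7-2, and 1281 had an unadjusted p under 0.05. The share with an unadjusted p under 0.05 in the authors' deposited table was 6.09% of the 15352 features at the minimum and 1.70% of the 20372 below it, where few reads limit the p that can be reached. The adjusted p in the authors' deposited table was under 0.05 for 24 of the 121 and 15 of the 144. MTR_3g072500 rose from 43.8 to 1003 normalised reads (adjusted p of 1.05e-08 in the authors' deposited table) and MTR_6g071430 from 35.3 to 763 (1.76e-06). MTR_2g097580 fell from 1473 to 65.1 (adjusted p of 1.05e-08 in the authors' deposited table) and MTR_8g031120 from 918 to 107 (0.0156). Leaving out 1 component moved the fold of MTR_3g072500 from 22.9 to between 14.8 and 50.5, of MTR_6g071430 from 21.6 to between 14.4 and 38.8, and of MTR_2g097580 from 22.6 to between 13.8 and 63.1. Of the 8 highest and the 8 lowest ratios at a mean of at least 200, 3 each had an adjusted p under 0.05 in the authors' deposited table.

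The 4-fold counts need to be read against the spread between components of 1 genotype, which exceeded counting error. The components differed beyond the 95% limit of counting error in 59.6% of genes in A17 and 51.4% in dnf7-2, where counting error alone gives 5%. Set against each other, the A17 components differed at least 4-fold in 585 genes and the dnf7-2 components in 301, while the 4 pairs across genotypes gave 362 to 959. Components did not overlap between genotypes in 44.2% of genes; the share would be 33.3% by chance if the 4 components were exchangeable, which the labels do not state. Deeper-minus-shallower differences correlated between the genotypes (Pearson r of 0.31 across the 15352 genes), which goes against it, so 33.3% is a rough guide only. Under scaling to column totals the counts were 189 higher and 111 lower, so the share of higher genes went from 45.7% to 63.0%. Leaving out the deeper A17 component gave 241 higher and 234 lower, the shallower A17 component 419 and 158, and the shallower dnf7-2 component 172 and 443.

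The most abundant transcripts took a smaller share of the dnf7-2 mean, by an amount that depends on where they are chosen. The 10 most abundant features of A17 took 7.60% of its mean and 4.45% of the dnf7-2 mean. The 10 most abundant features of dnf7-2 took 6.52% of the A17 mean and 5.53% of the dnf7-2 mean, a smaller gap. In the components, the share of the A17 features was 6.94% and 8.25% in A17, and 4.12% and 4.76% in dnf7-2. NCR-named features together took 0.122% in A17 and 0.0709% in dnf7-2, the signalling group 0.287% and 0.198%, and the persistence loci 0.244% and 0.111%. The dnf7-2 components differed in these shares, with 0.148% and 0.245% for the signalling group and 0.0739% and 0.145% for the persistence loci. The persistence loci include NCR169, the mutated gene. It held 7879 of their 24378 normalised reads in A17 and 10.9 of 9713 in dnf7-2. Of the 50 features with the highest mean, 17 were at least 2-fold lower in dnf7-2, 0 were at least 2-fold higher, and 1 had an adjusted p under 0.05 in the authors' deposited table.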

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

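The reads on rows without a gene name were singled out after the table was seen. The 4 rows of the deposited table that name no gene held 599 reads, 279 and 167 in the A17 components and 128 and 25 in the dnf7-2 components. This is above the limit that a count of 0 allows, in rows that no comparison of the report uses. In the authors' deposited table each of the 4 has an adjusted p of 1.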

How the results depend on the processing

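The leave-outs of components, the list without NCR169, the order of rows, the restriction to genes with separated components and every alternative for single named genes other than NCR169 were chosen after the data were seen; the others were planned. The NCR-named median stayed below all random lists under every alternative run, from -1.34 to -0.81 over the 4 leave-outs. The alternative scalings could not have changed this place, since each moves every log2 ratio by nearly the same amount. Counts of genes at least 4-fold higher and lower were 189 higher under column totals, 614 and 613 with no minimum, 59 and 75 at a mean of at least 200, 957 and 995 at 2-fold, and 144 to 419 and 137 to 443 over the leave-outs. The signalling median was -0.44 (percentile 2.13) with no minimum and -0.42 (percentile 1.12) against unmatched lists, where it stood apart, and -0.79 to -0.29 over the leave-outs. The persistence median was -0.94 without NCR169 and -1.62 to -0.57 over the leave-outs. NCR169 ranged from 0.0424% to 0.235% of A17 over the leave-outs. The longest silent run was 2 loci, at an A17 mean of at least 10, and the run holding NCR169 was 1 throughout. Those 2 loci, MTR_7g028553 and MTR_7g028557, are on chromosome 7, as is NCR169 (MTR_7g029760). By identifier, MTR_7g029630, which was not silent, lies between them and NCR169. Without the 10 most abundant features of either genotype, each genotype's own top 100 took 14.7% in A17 and 12.1% in dnf7-2. With those features kept, the top 100 took 21.0% and 16.4%. Without them, NCR-named features took 0.134% and 0.0754%, the signalling group 0.314% and 0.211%, and the persistence loci, NCR169 included, 0.267% and 0.118%. The lists' shares are higher because the total is smaller, and the top 100 lower because its leading members are gone. Apart from these and the thresholds, the cause was not tested. For single named genes, 129 values moved beyond their counting interval and 125 did not.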

Other observations

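The tests below were planned before their values were seen, except those of the shared preparation batch, of r without 2 members, of crossed components and of neighbouring loci, which were chosen after; that an interval, not the value alone, had to pass a bound was settled after first values were seen. In 15014 pairs of neighbouring loci on a chromosome, log2 ratios correlated with a Pearson r of 0.11 across genes, above the upper limit of 0.0167 over 1000 shuffled orders, and r was -0.01 at 10 loci apart. At 50 loci apart r was 0.0237, above its shuffled limit of 0.0166. Genes are not independent replicates. The highest ratio at a mean of at least 200 rested on 1 component, with 2615 reads in the deeper and 2 in the shallower dnf7-2 component.

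For the lower NCR-named features (median log2 ratio -0.85), the higher of the medians under column totals and the trimmed mean was -0.67 (95% bootstrap interval -1.16 to -0.51). These scalings raised log2 ratios by about 0.19 and 0.026, too little to bring the median to 0. This argues against a choice among these scalings as the whole cause. The interval resamples genes and does not measure error in scaling, so other scalings were not tested by it. A single component library is argued against by the leave-out median nearest 0, -0.81 (-1.41 to -0.47). A biological hypothesis is that dnf7-2 nodules hold fewer cells that express these genes. Against a uniform loss, member ratios correlated between the deeper and the shallower pair with r = 0.59 (permutation p = 0.00354, one-sided, across 20 genes), past the bound of 0.5 set in advance, but the interval of 0.27 to 0.83 spans that bound, r was 0.47 without the 2 farthest members and 0.16 with the components crossed, and all other genes gave 0.40. A uniform loss and unequal changes of single genes cannot be told apart here, and no marker list for other cell types could be used.

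Of the 265 genes at least 4-fold apart, 226 had no adjusted call in the authors' deposited table. In the genotype with the higher mean, their components differed by a median of 0.97 on the log2 scale, against 0.34 in the 39 called genes. The difference of 0.63 (0.43 to 0.80) passed the bound of 0.5 set in advance but its interval spans it, and it decides little, since a test that weighs spread within a genotype withholds calls where that spread is large. Fewer reads stay open as well, with a ratio of median reads of 0.507 (0.265 to 1.05). No biological explanation was tested for this pattern.

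Gene by gene, the deeper-minus-shallower log2 difference in A17 correlated with that in dnf7-2. Across 1888 genes with a mean of at least 1000, r was 0.35 (0.28 to 0.43). Counting noise is drawn separately in each library and would not by itself make these differences correlate. The r of 0.35 (0.28 to 0.43) therefore argues against counting noise alone as the cause of the correlation in these 1888 genes. A preparation or sequencing batch shared by the deeper and by the shallower libraries may give r = 0.31 across the 15352 genes, but no label names a batch, so batch and depth cannot be told apart. No biological explanation was tested for this pattern.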
